A study of Mus musculus with 4 samples.

How the data were processed

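Testis cells of mice were profiled with droplet-based 3' single-cell RNA sequencing (10x Genomics, v3 chemistry, per the labels' protocols), a method that tags each captured transcript with a cell barcode and a unique molecular identifier (UMI). The labels describe 4 libraries, from wild-type and Stra8-deficient testis at days 10 and 21. A count matrix was used for 2 of them, wild type at day 10 and Stra8-deficient at day 21, and the other 2 were not analysed here. Genotype and age therefore differ together between the libraries compared, with 1 library each, so no difference between them was assigned to genotype or to age, and no p-value was computed. The labels' extraction text names digestion of an aging ovary, while the titles, source names and tissue fields name testis; the tissue was taken as testis from the latter.

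The deposited matrices hold raw UMI counts per gene and barcode before any cell calling, made with Cell Ranger 6.0.1 on the mm10 build, per the submitters' processing notes. The gene annotation release is not given in the sources used here. The feature list has 32286 entries, of which the last is EGFP (a green fluorescent protein sequence that the labels do not mention). Symbols carried by several gene identifiers were kept apart by identifier. Gene positions were looked up by Ensembl identifier in GENCODE M21 on GRCm38, the assembly of mm10, and are 1-based.

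Barcodes were kept as cells when they had at least 1000 UMIs, at least 500 detected genes and at most 10% mitochondrial UMIs. The last limit caps the summed level of the mitochondrial genes in every class and so bounds their ratios. Doublets were called per library with Scrublet as run by scanpy 1.11.5 and removed. Counts were scaled to 10000 UMIs per cell and log-transformed, 2000 variable genes were taken, and cells of both libraries were clustered together on 30 principal components with 15 neighbours and the Leiden method at resolution 1. The genes of the 20 gene lists (none of them a marker), Stra8, EGFP, Xist, Y-linked, mitochondrial and ribosomal protein genes were kept out of the variable genes, and EGFP was added to these once the feature list had been read. Germ clusters were clustered again in the same way. The software was Python 3.11.15 with anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.

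Clusters were named from markers of 13 cell classes and are called "like" those classes, since no deposited annotation was used. The class with the highest mean standardised marker level was taken when at least 3 of its markers were detected (a UMI in at least 10% of cells and a level above that of the other clusters), and when the 10 genes with the highest fold held no more markers of other classes than of its own, the germ classes counting as the same class until germ cells were clustered again. A cluster whose median UMI count was under 1/3 of that of the libraries of its cells was held to a further rule. It stayed unnamed unless a marker of its best-scoring class, with germ classes not pooled, was among those 10 genes. The markers, gene lists, filters, contrasts, the rule for named genes and 16 alternative settings were fixed before the data were examined. The scoring rule for naming was not: it was settled after cluster tables had been seen that also printed Stra8, Slc7a5, Slc38a2 and Slc2a1. In all, 3 versions were tried, the last was kept for its treatment of clusters with few UMIs, and the earlier versions were run as added alternatives.

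UMIs were summed per library and class and divided by the total of all genes, giving CPM (counts per 1000000 UMIs). Levels carry exact Poisson 95% intervals and shares of cells carry exact Clopper-Pearson 95% intervals. Both cover counting error only, not the spread between animals, and for a count of 0 the limit of 3 counts is given. Ratios are log2 values with a pseudocount of 1 CPM, which understates changes of low genes. Each gene list was summarised by the median ratio of its members with at least 5 CPM in either sum, with a 95% interval from 2000 resamplings of its members. The percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins, describes these libraries and is no test of the conditions. Ratios of early meiotic-like over undifferentiated-like and over differentiating-like cells were taken within each library. Ratios of the deficient over the wild-type library were taken within each germ class and, as a somatic reference, in Sertoli-like cells, for classes of at least 30 cells. The difference of the stage ratios between libraries was computed as well but not run under the alternatives, and is not reported here.

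The lists covered amino acid importers, glucose and monocarboxylate transporters, glycolysis, TCA cycle and pyruvate entry, nuclear and mitochondrial genes of oxidative phosphorylation, fatty acid oxidation, glutamine and glutamate enzymes, amino acid response, mTORC1 components, cholesterol synthesis, ribosome biogenesis, proteasome, autophagy and lysosome, meiotic prophase, DNA replication, mitosis, p53 response and apoptosis, retinoid pathway and dissociation stress. Stra8, Slc7a5, Slc38a2 and Slc2a1 were always named. For each list, the rule named the 2 members with the highest and the 2 with the lowest ratio among members with at least 50 UMIs in both sums together and 20 CPM in either. Between libraries it also named the 8 highest and 8 lowest ratios of all genes with at least 50 UMIs, 100 CPM in either sum and intervals that did not overlap, without markers, mitochondrial, ribosomal protein and predicted genes. After many single-gene values were seen to change sign under the alternatives, rule-picked genes were limited to the early meiotic over undifferentiated ratios of each library and the early meiotic ratio between libraries, and no such genes are given for the other contrasts. Some genes that the rule picked are not reported here.

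The ratio and list calculations were tested on simulated data with the mean levels of 17090 genes in the wild-type early meiotic-like and undifferentiated-like cells, 200 of them changed. Counts were drawn from the Poisson model that the intervals assume, so the test checks the calculation and not the spread between cells. The changed genes had a mean level of at least 100 CPM. The median ratio was 0.99 for genes simulated at a log2 ratio of 1 and -2.00 for genes simulated at -2. Among genes of at least 100 CPM, 94.9% of the intervals held the simulated value, and genes of lower level were not counted there. Of 100 lists of unchanged genes, 4% fell outside the central 95% of random lists. Alternatives fixed beforehand changed the UMI minimum, the mitochondrial limit, doublet removal, the clustering resolution, joint clustering, the variable genes, the depth per cell, the averaging, the subtraction of free RNA, the pseudocount, the minimum level of list members, the genes in the total and the rule for calling cells. A further 7 alternatives were added after seeing the data, namely another random seed, the earlier naming versions, a class for unnamed germ clusters, a second profile of free RNA and the cluster held by both libraries alone.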

Results

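Single-cell transcriptomes of mouse testis were compared in 2 libraries, 1 from wild-type testis at day 10 and 1 from Stra8-deficient testis at day 21. The title of the series asks how metabolic gene expression changes as male germ cells enter meiosis, and Stra8 encodes a retinoic acid-responsive regulator of that entry. The wild-type matrix held 71963187 UMIs over 1539250 barcodes, and the deficient matrix held 64338155 over 1452552. Barcodes with at least 1000 UMIs numbered 4784 and 3337, and 1940 of the former (40.6%) and 1333 of the latter (39.9%) exceeded the mitochondrial limit. Doublet calls removed 80 barcodes (3.11%) from the wild-type library and 29 (1.67%) from the deficient library. The remaining 2495 wild-type cells had a median of 10899 UMIs and 3257 genes, and the 1708 deficient cells had 4199 UMIs and 1891.5 genes. UMIs in barcodes under 1000 UMIs made up 19.9% of the wild-type total and 42.3% of the deficient total. There was no replicate library. Intervals given in brackets are 95% intervals of counting error for levels and shares, and of resampled members for gene lists.

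Stra8 was lower in every germ class of the deficient library. Its level in wild-type cells was 45.4 CPM (37.3 to 54.7) in undifferentiated spermatogonia-like cells, 373 (353 to 394) in differentiating spermatogonia-like cells and 569 (524 to 617) in early meiotic-like cells. In deficient cells the corresponding levels were 15.3 CPM (11.2 to 20.5), 10.4 (7.15 to 14.6) and 32.7 (28.5 to 37.4). Wild-type Stra8 was uneven within classes. Of its 1241 UMIs in differentiating-like cells, 1011 lay in the 38 cells of germ cluster 10 (623 CPM, against 103 in cluster 5), and of its 587 UMIs in early meiotic-like cells, 440 lay in the 23 cells of germ cluster 11 (1388 CPM, against 214 in cluster 4). The early meiotic ratio of deficient over wild type was -4.08 on the log2 scale. Under the alternatives the early meiotic-like level ran from 569 to 1388 CPM in the wild-type and from 28.3 to 51.9 CPM in the deficient library. The main wild-type level thus lay at the low end of its range. Sertoli-like cells, the somatic nurse cells of the tubule, gave the background, at 0.715 CPM (0.287 to 1.47) in the wild-type and 0.492 (0.0125 to 2.74) in the deficient library. Stra8 lies on chromosome 6 from 34920163 to 34939344 on the plus strand (GRCm38). The labels do not say which part of the gene is altered, and 3' reads need not cover it, so a residual level does not check the genotype.

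**Figure D1:**
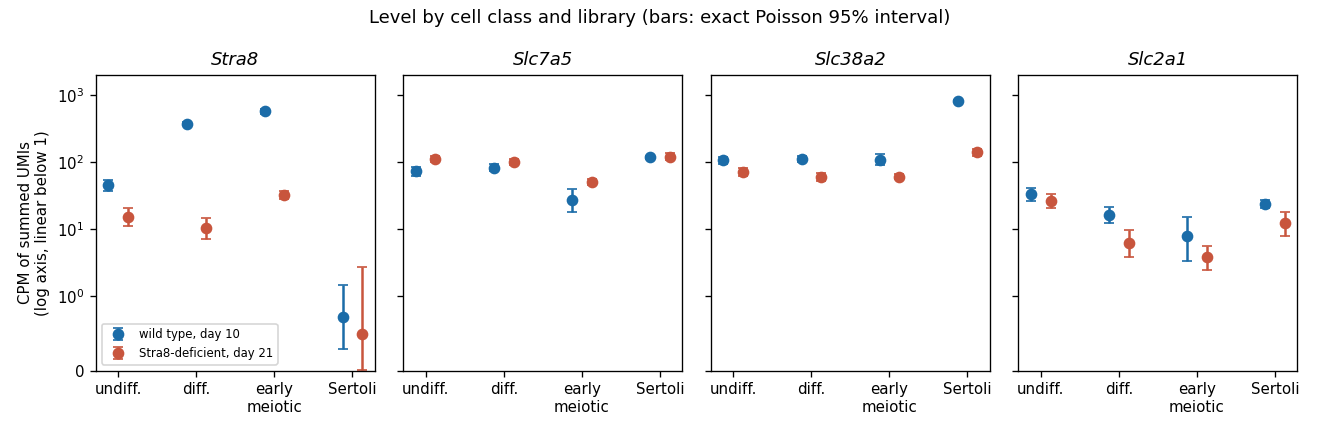
Levels of Stra8, Slc7a5, Slc38a2 and Slc2a1 in CPM of summed UMIs (log axis, linear below 1) in 3 germ classes and Sertoli-like cells, with points for the wild-type day 10 and Stra8-deficient day 21 libraries and bars for exact Poisson 95% intervals. Early meiotic-like Stra8 stood at 569 CPM in the wild-type and 32.7 CPM in the deficient library.

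Germ cells with a class name made up 9.62% of wild-type cells (8.49 to 10.8, 240 cells) and 22.5% of deficient cells (20.6 to 24.6, 385 cells). Early meiotic-like cells, a class named mainly from transcripts of the chromosome axis and of recombination, were 25.8% of the named germ cells in the wild-type library (20.4 to 31.9, 62 cells) and 60.0% in the deficient library (54.9 to 64.9, 231 cells). Undifferentiated spermatogonia-like cells, the class that holds the stem cells, were 33.8% (81 cells) and 13.8% (53 cells). These shares leave out the germ clusters that stayed unnamed, whose best-scoring class was undifferentiated spermatogonia. Differentiating spermatogonia-like cells were 40.4% (97 cells) and 26.2% (101 cells). No cluster took a name of pachytene or later spermatocytes or of spermatids, and a few such cells inside another cluster would not have been seen.

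Most germ clusters came largely from 1 library, so a cluster may stand for its library and not for a cell type. Early meiotic-like cells of the deficient library were mainly in germ clusters 1 (64 cells), 3 (86 cells) and 6 (50 cells), none of which had more than 4 wild-type cells. Those of the wild-type library were in cluster 11 (23 cells, none from the deficient library) and in cluster 4, which both libraries shared with 35 wild-type and 31 deficient cells. Cluster 4 had 7 early meiotic markers detected, but its 10 leading genes held Cdc25b, Cdkn3, Knstrn and Hmmr and none of those markers. Among the early meiotic-like clusters only cluster 11 had such a marker, Prdm9, among its leading genes. Undifferentiated-like cells were mainly in cluster 9 for the wild type (76 of 81 cells) and in cluster 0 for the deficient library (45 of 53). Cluster 9 held the markers Gfra1, Etv5 and Ret among its 10 leading genes. Cluster 0 had 9 markers of that class detected but none among its leading genes. Stage ratios over undifferentiated-like cells therefore rest on different clusters in each library. Differentiating-like cells were mainly in clusters 5 (48) and 10 (38) for the wild type and in clusters 2 (61) and 8 (34) for the deficient library. A further 134 wild-type germ cells (5.37%) and 3 deficient germ cells (0.176%) stayed without a class, in clusters whose 10 leading genes held haemoglobin genes, Sertoli markers or a marker of differentiating spermatogonia. The best-scoring class of these clusters (7, 12 and 13) was undifferentiated spermatogonia, with 7, 8 and 1 of its markers detected. Their cells are in neither the undifferentiated-like share nor the stage ratios. Across the clustering alternatives the early meiotic-like share ran from 7.08% to 26.0% in the wild-type and from 29.7% to 75.4% in the deficient library. The main wild-type share of 25.8% lay near the top of its range, and most alternatives fell below its interval. Cluster 4 held 35 of the 62 wild-type cells of the class, so the wild-type stage ratios rest largely on it.

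Among somatic cells, Sertoli-like cells were 21.8% of the wild-type and 35.5% of the deficient library, with median depths of 13600 and 1931 UMIs. Peritubular myoid-like cells, the contractile cells around the tubule, were 27.9% and 3.16%, and interstitial stromal-like cells were 22.8% and 12.6%. The myoid-like clusters 20 and 21 of all cells, with 80 and 284 wild-type cells, had 6 myoid markers detected but none among their 10 leading genes. Those of cluster 20 held Rgs5, Cox4i2, Ndufa4l2 and Notch3, so the myoid-like class may hold other cells as well. Leydig-like cells, which make testosterone, were 2.85% and 3.28%, macrophage-like cells 1.12% and 0.644%, and endothelial-like cells 0.681% and 0.351%. The macrophage-like cluster had 7 macrophage markers detected, but its 10 leading genes held S100a8, S100a9, Ngp and Camp and none of those markers. It may therefore hold other cells as well. No cluster was named lymphocyte-like or erythroid-like. Cells without a name, mostly of low depth, were 7.78% of the wild-type (194 cells) and 21.8% of the deficient library (372 cells). Most of the latter were in cluster 3 of all cells (367 deficient and 71 wild-type cells, median 1691.5 UMIs), whose best-scoring class was differentiating spermatogonia. Its 10 leading genes held Utf1, a marker of undifferentiated spermatogonia, but no marker of its best-scoring class. These cells are not in the named germ shares, and whether their germ transcripts came from free RNA was not determined.

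In wild-type testis, early meiotic-like cells had lower levels of glycolytic and cholesterol synthesis genes than undifferentiated-like cells. Of 14 measured glycolysis genes 13 were lower, with a median log2 ratio of -2.16 (-3.24 to -1.31). Of 15 cholesterol synthesis genes 14 were lower, with a median of -1.17 (-1.89 to -0.53). Of 39 meiotic prophase genes 33 were higher, with a median of 1.54 (1.06 to 2.01). None of them was a marker, but the class was named from other meiotic genes, so a higher median follows from the naming in both libraries. The first of these medians lay at percentile 0.01 of matched random lists, the second at 0.00 and the third at 100, against a median of 0.17 over 7148 genes with at least 20 CPM. With the 1 glycolysis gene that had 0 UMIs in early meiotic-like cells set at its limit, the glycolysis median was -2.15. The cholesterol synthesis median moved to -2.07 at clustering resolution 0.6, -2.25 with each library clustered alone and -2.32 under the second naming version.

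Within glycolysis, the aldolase gene Aldoa stood at 20.4 CPM in early meiotic-like against 231 CPM in undifferentiated-like cells. Aldoc, another aldolase, had 2 UMIs in early meiotic-like cells (1.94 CPM against 43.8, log2 ratio -3.93, counting interval -7.56 to -2.61), and Pgk1, the phosphoglycerate kinase, was the exception at 28.1 against 11.6 CPM. Gapdh was lower at 486 against 751 CPM. Within cholesterol synthesis, the mevalonate decarboxylase gene Mvd stood at 4.85 against 31.0 CPM. Among meiotic prophase genes, Meioc, which is required to hold the meiotic programme, stood at 569 against 5.78 CPM. Gm4969, the symbol in the deposited files for Meiosin (the DNA-binding partner of Stra8, chromosome 7, 19099046 to 19118368, minus strand), stood at 51.4 against 2.89 CPM. Topaz1 and Mnd1 went the other way, at 28.1 against 96.6 and 11.6 against 40.5 CPM.

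Amino acid importers were mixed in the wild-type library, with 8 of 14 measured genes lower and a median of -0.87 whose interval held 0 (-1.78 to 0.69, percentile 3.46). Slc7a5, the light chain of a large neutral amino acid exchanger (chromosome 8, 121881150 to 121907694, minus strand), was lower at 27.2 CPM (18.0 to 39.2) against 72.7 (62.3 to 84.2). Slc38a1, a glutamine transporter, had 0 UMIs in early meiotic-like cells, which allows up to 2.91 CPM, against 21.9 CPM. Slc7a6 and the lysosomal transporter Slc38a9 were higher, at 33.0 against 10.3 and 66.9 against 35.9 CPM. Slc38a2, another glutamine transporter (chromosome 15, 96687392 to 96699730, minus strand), had overlapping intervals at 109 CPM (89.4 to 131) and 106 CPM (93.9 to 120). The glucose transporter Slc2a1 (chromosome 4, 119108711 to 119137983, plus strand) was lower at 7.76 CPM (3.35 to 15.3) against 33.4 (26.6 to 41.6). Slc7a5, Slc38a2 and Slc2a1 were chosen by the study on these samples, so they are not independent evidence of a direction.

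Lists of mitochondrial energy genes lay near the all-gene median. The 45 nuclear genes of oxidative phosphorylation had a median of 0.16 (-0.054 to 0.23), with Ndufa1 of complex I higher at 295 against 57.0 CPM and Cox8a of complex IV lower at 177 against 843 CPM. The 13 mitochondrial genes had a median of -0.16 (-0.26 to -0.045, percentile 24.1), with mt-Nd1 at 2782 against 4617 CPM. TCA cycle and pyruvate entry genes had a median of 0.31 (-0.16 to 0.59), with the pyruvate carrier gene Mpc1 at 238 against 60.3 CPM and the pyruvate dehydrogenase gene Pdha1 at 9.70 against 52.8. Fatty acid oxidation genes had a median of 0.0092 (-0.54 to 0.74), with Etfa higher at 188 against 41.3 CPM and Acaa2 at 0 UMIs (up to 2.91 CPM) against 28.9. Glucose and monocarboxylate transporters had a median of -0.021 (-2.74 to 1.85), and the thyroid hormone and aromatic amino acid transporter Slc16a10 was higher at 36.8 against 6.19 CPM. Glutamine and glutamate enzymes had a median of -0.080 (-2.36 to 0.84), with the ornithine aminotransferase gene Oat at 153 against 31.8 CPM and Glul, the glutamine synthetase, at 35.9 against 115. The median of these enzymes was -2.74 at clustering resolution 1.5.

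Proteasome and ribosome biogenesis genes were lower. Proteasome genes had a median of -0.55 (-0.78 to -0.31, 12 of 14 lower), with Psma5 at 142 against 308 CPM. The proteasome median was -1.35 at clustering resolution 1.5. Ribosome biogenesis genes had a median of -0.33 (-0.52 to -0.098, 14 of 18 lower), with Mybbp1a at 57.2 against 181 CPM. The amino acid response list had a median of -0.72 with an interval that held 0 (-1.09 to 0.039, 10 of 15 lower), and the serine synthesis enzyme gene Phgdh stood at 50.4 against 237 CPM. mTORC1 components had a median of 0.32 (-0.24 to 0.89), and autophagy and lysosome genes -0.087 (-0.66 to 0.40). Retinoid pathway genes were higher at a median of 1.20 (0.28 to 1.52, 7 of 8, percentile 98.9), with the retinaldehyde dehydrogenase gene Aldh1a2 at 34.9 against 11.6 CPM. Mitosis genes, at 0.35 (0.098 to 0.75, 13 of 16 higher), lay within the range of matched random lists (percentile 77.8). DNA replication genes at -0.032 (-0.51 to 0.80), p53 response and apoptosis genes at 0.35 (-0.38 to 1.82) and dissociation stress genes at -0.99 (-2.08 to 0.50) had intervals that held 0. The wild-type nuclear oxidative phosphorylation median turned to -0.33 at clustering resolution 1.5, the mitosis median to -1.15 at resolution 0.6 and the retinoid median to -0.42 with the mitochondrial limit at 20%. The retinoid median shrank to 0.051 under the second naming version and 0.13 with shallow germ clusters kept under the first. It was 0.27 with unnamed germ clusters given their best class. The importer median moved to -2.34 when each library was clustered alone.

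**Figure D2:**
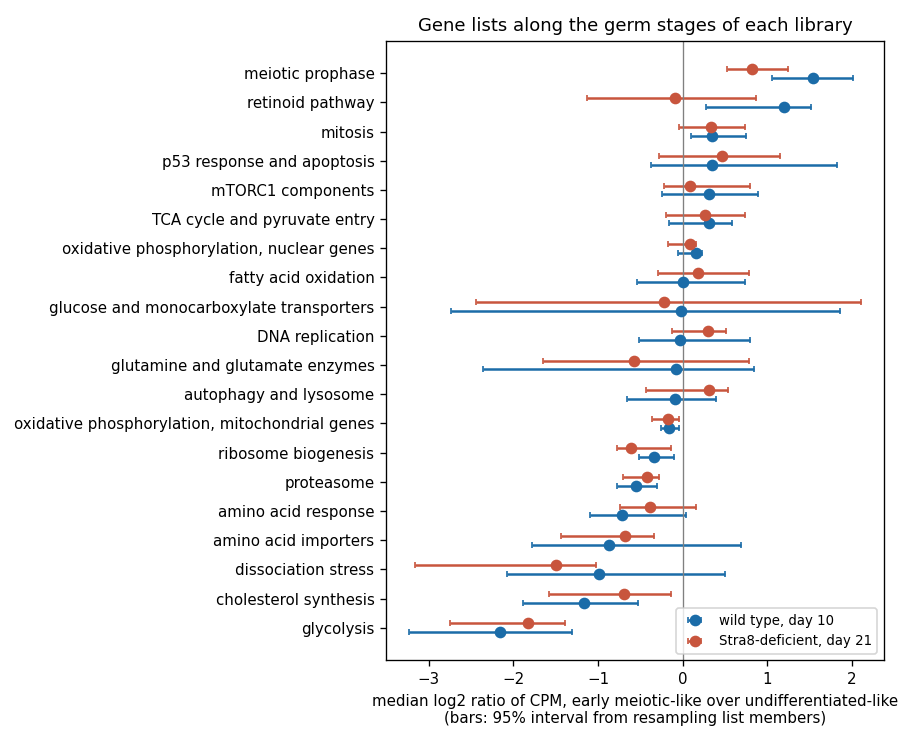
Median log2 ratio of CPM of early meiotic-like over undifferentiated-like cells for 20 gene lists, with points for the wild-type day 10 and Stra8-deficient day 21 libraries and bars for 95% intervals from resampling list members. Glycolysis had the lowest median in both libraries (-2.16 and -1.83) and meiotic prophase the highest (1.54 and 0.82).

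In the deficient testis, the same stage comparison again gave lower glycolysis genes. Glycolysis genes had a median of -1.83 (-2.75 to -1.39, 14 of 15 lower), with the lactate dehydrogenase gene Ldha at 1.23 against 28.3 CPM and the hexokinase gene Hk1 at 3.99 against 44.3. Meiotic prophase genes had a median of 0.82 (0.53 to 1.25, 32 of 39 higher), with Meioc at 353 against 16.7 CPM and Gm4969 at 24.0 against 3.07. Amino acid importers had a median of -0.69 (-1.44 to -0.34, 16 of 20 lower, percentile 3.84), with the taurine transporter gene Slc6a6 at 0.768 against 39.9 CPM and Slc36a4 higher at 28.3 against 11.2. Slc7a5 was lower at 50.4 CPM (45.1 to 56.1) against 111 (99.3 to 124), and Slc2a1 was lower at 3.84 (2.49 to 5.67) against 26.2 (20.7 to 32.8). Slc38a2 had overlapping intervals at 60.7 CPM (54.8 to 67.0) and 70.9 (61.6 to 81.2).

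Cholesterol synthesis genes were lower in these cells at a median of -0.69 (-1.58 to -0.14, 12 of 15), with the farnesyl diphosphate synthase gene Fdps at 83.9 against 299 CPM. Ribosome biogenesis genes were lower at -0.62 (-0.77 to -0.14, 13 of 18) and proteasome genes at -0.42 (-0.71 to -0.28, 12 of 14), with Mybbp1a at 73.4 against 265 CPM and Psmb6 at 185 against 448. Dissociation stress genes were lower at -1.50 (-3.17 to -1.02, 11 of 11), with the immediate early genes Egr1 at 7.83 against 193 CPM and Fos at 7.53 against 75.6. Mitochondrial genes of oxidative phosphorylation were at -0.18 (-0.37 to -0.042, 10 of 13 lower, percentile 26.03), within the range of matched lists. The p53 targets Bbc3, which promotes apoptosis, and Cdkn1a, which halts the cell cycle, were higher at 49.2 against 4.43 and 24.3 against 5.45 CPM, in a list whose median was 0.47 (-0.28 to 1.15). That list median was -0.46 with the mitochondrial limit at 20% and -0.51 at clustering resolution 0.6.

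A further 11 lists had intervals that held 0 in the deficient library. Their medians were 0.088 for nuclear oxidative phosphorylation, 0.26 for TCA cycle and pyruvate entry, 0.18 for fatty acid oxidation, -0.22 for glucose and monocarboxylate transporters and -0.57 for glutamine and glutamate enzymes. They were -0.38 for the amino acid response, 0.082 for mTORC1 components, 0.32 for autophagy and lysosome, 0.30 for DNA replication, 0.33 for mitosis and -0.096 for the retinoid pathway. Within them, Ndufa1 stood at 318 against 94.7 CPM, Mpc1 at 126 against 40.5 and Rrm2 (a ribonucleotide reductase subunit) at 87.9 against 14.0. The all-gene median was 0.13 over 7995 genes. The nuclear oxidative phosphorylation median turned to -0.18 and the Cdkn1a ratio to -0.012 at clustering resolution 0.6, and the median of the mitochondrial genes to 0.21 with the mitochondrial limit at 20%.

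Against differentiating-like cells, wild-type early meiotic-like cells had lower importer, glycolysis and cholesterol synthesis genes. The importer median was -1.44 (-1.71 to -0.034, 11 of 15 lower, percentile 0.06). It was -0.90 with the 2 importers that had 0 UMIs in early meiotic-like cells set at their limit. Glycolysis genes had a median of -1.66 (-2.59 to -0.67, 11 of 12 lower) and cholesterol synthesis genes -1.04 (-1.80 to -0.66, 15 of 15 lower). Amino acid response genes were at -0.74 (-1.42 to -0.50), proteasome genes at -0.65 (-0.77 to -0.24), ribosome biogenesis genes at -0.52 (-0.81 to -0.13) and meiotic prophase genes at 1.41 (0.89 to 1.81). Dissociation stress genes moved the same way, at -0.89 (-1.22 to -0.079, 10 of 12 lower, percentile 0.19) and at -1.43 with the mitochondrial limit at 20%. Mitosis genes were at 0.33 (0.13 to 0.56, percentile 89.5) and turned to -1.21 at clustering resolution 0.6.

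Deficient early meiotic-like cells set against differentiating-like cells also had lower glycolysis genes, at -1.18 (-1.62 to -0.41, 11 of 12). The importer median of -0.36 had an interval that held 0 (-0.99 to 0.072, 9 of 15 lower, percentile 6.0). DNA replication genes, which include the MCM helicase, were lower at -0.47 (-0.76 to -0.25, 16 of 18), proteasome genes at -0.49 (-0.65 to -0.28), ribosome biogenesis genes at -0.44 (-0.81 to -0.23) and cholesterol synthesis genes at -0.26 (-0.92 to -0.13). Meiotic prophase genes were higher at 0.58 (0.47 to 0.88). The glycolysis median depended on the clustering. It was -0.024 at clustering resolution 0.6, -0.21 with the mitochondrial limit at 20% and -0.29 with list genes among the variable genes. With doublets kept it was -0.32, and under another random seed -0.39. The DNA replication and cholesterol medians turned to 0.089 and 0.11 with a minimum of 500 UMIs. The ribosome biogenesis median shrank to -0.10 at resolution 1.5, -0.13 with a minimum of 500 UMIs and -0.21 with doublets kept.

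Between libraries, early meiotic-like cells differed in Stra8, in the immediate early gene Fos and in genes of several other functions. Apart from Stra8, the lowest ratios of deficient over wild type among genes with at least 100 CPM in either library, markers left out, were those of Fos (7.53 against 130 CPM, log2 ratio -3.94), the homeobox gene Pbx3 (14.4 against 111), the signal peptidase gene Sec11c (28.1 against 111) and the chromatin gene Ing2 (32.4 against 124). The NF-kB gene Rel, the Polycomb gene Cbx8 and the deubiquitinase gene Cyld followed at log2 ratios of -1.43, -1.38 and -1.37. The highest ratios under the same limits were those of Camk2n1, an inhibitor of CaM kinase II (150 against 33.0 CPM, 2.15), Txnip, a thioredoxin-binding protein gene (111 against 25.2, 2.10), Ktn1 (108 against 27.2, 1.96) and the growth factor receptor gene Igf1r (142 against 37.8, 1.89). Tnrc6a, Msi2 and Ptp4a3 followed at 1.68, 1.63 and 1.58, as did Hist1h2ap at 1.55, whose reads are uncertain because histone genes are near-identical. Each value was read against an all-gene median of 0.21 over 7242 genes. Pbx3 was a leading gene of germ cluster 11 (23 wild-type and 0 deficient cells), and Hist1h2ap of cluster 6 (4 and 50 cells). Their ratios may therefore restate which clusters make up the class in each library.

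Dissociation stress genes were lower in the deficient early meiotic-like cells at a median of -1.53 (-3.04 to -0.45, 8 of 10, percentile 0.00), with Fosb at 1.54 against 47.5 CPM. p53 response and apoptosis genes were higher at 0.68 (0.42 to 0.79, 10 of 10, percentile 98.0), with Phlda3 at 32.3 against 14.5 CPM, Aen at 94.9 against 54.3 and Bax at 269 against 177. Glycolysis genes, at 0.73 (0.21 to 1.12, 8 of 10 higher, percentile 96.6), lay near the upper limit of matched lists, with Aldoa at 45.6 against 20.4 CPM and the pyruvate kinase gene Pkm at 120 against 60.1. Amino acid importers, at 0.63 (0.060 to 0.87, 9 of 11 higher, percentile 85.5), lay within the range of matched lists, whose median was 0.38 (-0.065 to 0.85). Slc7a5 stood at a log2 ratio of 0.87, Slc38a2 at -0.83 and Slc2a1, with overlapping intervals, at -0.86. Slc38a2 was also lower in somatic classes of the deficient library, as given below for Sertoli-like and other cells. In the germ cluster shared by both libraries the glycolysis median was 0.055 and the importer median 0.38, and Slc38a2 turned to 0.036 with the mitochondrial limit at 20%.

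Meiotic prophase genes had a median of -0.13 in this comparison (-0.26 to 0.044, 22 of 39 lower), at percentile 0.41 of matched lists. The cohesin gene Rad21l and the recombination gene Msh5 were lower, at 7.99 against 38.8 and 9.52 against 33.9 CPM. Mlh3, a mismatch repair gene of crossovers, and Topaz1 were higher, at 53.6 against 17.5 and 81.3 against 28.1 CPM. The median was 0.43 in the shared germ cluster and -0.59 with a minimum of 500 UMIs. Nuclear genes of oxidative phosphorylation were at -0.19 (-0.33 to -0.100, 32 of 45 lower, percentile 14.9), within the range of matched lists, whose median was -0.10, with Cox5a at 452 against 782 CPM. Mitochondrial genes, whose sum the mitochondrial limit on cells caps, were higher at 0.14 (0.078 to 0.32, 12 of 13, percentile 98.9), with mt-Nd3 at 2086 against 763 CPM. Their median was 0.45 with that limit at 20%. It was 0.068 after subtraction of free RNA, 0.062 with shallow germ clusters kept under the first naming version and 0.055 with a minimum of 500 UMIs. Proteasome genes, at -0.25 (-0.43 to -0.12, 12 of 14 lower, percentile 9.35), also lay within the range of their matched lists and turned to 0.16 with a minimum of 500 UMIs, which moved the nuclear oxidative phosphorylation median to -0.044. The cholesterol synthesis median was -0.056 (-0.55 to 0.32). The mitosis median was 0.0060 (-0.33 to 0.34), but 1.01 (0.57 to 1.16, 16 of 16 higher) in the shared germ cluster, 0.95 with a minimum of 500 UMIs and 0.81 with the mitochondrial limit at 20%.

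In undifferentiated-like cells, retinoid pathway genes were higher in the deficient library at a median of 1.49 (0.50 to 2.07, 7 of 8, percentile 99.9). The class came mainly from a different germ cluster in each library, so ratios within it may restate that difference. Amino acid importers, at 0.58 (0.40 to 1.21, 17 of 20 higher, percentile 81.0), lay within the range of matched lists, whose median was 0.43, with an all-gene median of 0.24. Dissociation stress genes had a median of -0.32 with an interval that held 0 (-1.31 to 0.032). Nuclear genes of oxidative phosphorylation were lower at -0.21 (-0.29 to -0.029, 30 of 45, percentile 1.07), and cholesterol synthesis genes had a median of -0.27 with an interval that held 0 (-0.75 to 0.087). Slc7a5 stood at 111 CPM in the deficient and 72.7 in the wild-type library, and Slc38a2 at 70.9 and 106.

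Differentiating-like cells of the deficient library had lower stress and cholesterol genes than those of the wild-type library, against an all-gene median of 0.23. Dissociation stress genes were at -2.0 (-2.92 to -0.78, 11 of 12 lower), cholesterol synthesis genes at -0.70 (-1.03 to -0.30, 12 of 15 lower) and proteasome genes at -0.37 (-0.47 to -0.27, 13 of 14 lower). DNA replication genes were at 0.42 (0.23 to 0.59, 17 of 18 higher), meiotic prophase genes at 0.45 (0.27 to 0.60, 27 of 36 higher) and mitosis genes at 0.42 (0.077 to 0.54, 13 of 16 higher). With a minimum of 500 UMIs the mitosis median turned to -0.14 and the DNA replication median was 0.041. The latter was 0.075 with the mitochondrial limit at 20% and 0.0089 at clustering resolution 1.5. Slc7a5 stood at 101 CPM (90.3 to 113) in the deficient and 82.4 (72.9 to 92.7) in the wild-type library, and Slc38a2 at 59.8 and 111.

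Sertoli-like cells, taken as a somatic reference, also differed between the libraries, with an all-gene median of 0.23. Dissociation stress genes were lower at -1.25 (-1.70 to -0.89, 12 of 12), cholesterol synthesis genes at -1.72 (-2.56 to -0.16, 12 of 15) and mitosis genes at -1.56 (-2.28 to -0.67, 12 of 13). Nuclear genes of oxidative phosphorylation were higher at 0.62 (0.55 to 0.85, 41 of 45, percentile 99.95). Proteasome genes, at 0.57 (0.36 to 0.71, 14 of 14 higher, percentile 92.6), and mitochondrial genes, at -0.58 (-0.74 to -0.46, 11 of 13 lower, percentile 4.03), lay within the range of matched lists. Slc38a2 stood at 139 CPM (123 to 156) in the deficient and 813 (796 to 831) in the wild-type library, and Slc7a5 at 121 and 118. Slc38a2 was also lower in deficient interstitial stromal-like (45.4 against 490 CPM), Leydig-like (170 against 534) and peritubular myoid-like cells (243 against 645). In free RNA it stood at 95.6 against 409 CPM, so its lower level was not particular to germ cells. Free RNA was estimated at 9.69% of the UMIs of the deficient and 3.73% of the wild-type Sertoli-like cells. Meiotic prophase genes, at 1.27 (0.34 to 2.18), turned to -0.59 once free RNA was subtracted, which moved the mitosis median to -3.94. Averaging over cells gave -0.56 for mitosis and -3.37 for stress genes, and a mitochondrial limit of 20% gave -3.58 for the latter. The Sertoli-like clusters were nearly specific to 1 library each and differed in depth.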

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

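Of the tests in this part, the comparison of EGFP with Sertoli-like cells was chosen after the levels had been seen, and the count of UMIs per cell was chosen before. EGFP, the last entry of the feature list and not mentioned in the labels, was a signal outside the comparisons of the report. Its level in named germ cells was 7.227 CPM in the wild-type library (49 UMIs in 33 of 240 cells) and 8.635 CPM in the deficient library (109 UMIs in 75 of 385 cells), above the limits that a count of 0 allows (0.442 and 0.238 CPM). Germ clusters were uneven. In the wild-type library 35 of the 49 UMIs lay in the 38 cells of differentiating-like cluster 10 (21.6 CPM, 15.03 to 30.01), and clusters 5 and 9 stood at 1.30 and 1.82 CPM. In the deficient library clusters 0 and 1 held 42 and 34 of the 109 UMIs, and differentiating-like cells stood at 2.83 CPM (1.30 to 5.38). In Sertoli-like cells it had 0 UMIs in the wild-type library, which allows up to 0.306 CPM, and 0.492 CPM in the deficient library. Free RNA held 0.651 and 6.03 CPM of it.

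Free RNA as the whole source is argued against by the Sertoli-like cells, whose highest upper limit of 2.743 CPM lay below the lower limits in named germ cells, 5.35 CPM in the wild-type and 7.09 CPM in the deficient library. Carry-over held by a few cells is argued against by the spread over cells, since the 5 cells with the most EGFP held 13.92% of its 158 UMIs. A transgene in the mice, reads of another sequence placed on EGFP and carry-over spread thinly over many germ cells stay open, and none was tested. No biological explanation was tested, since the labels name no reporter.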

How the results depend on the processing

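The 7 alternatives chosen after seeing the data were another random seed, the 3 runs of earlier naming versions, the class given to unnamed germ clusters, the free RNA profile from barcodes of 200 to 500 UMIs and the shared cluster alone, and the other 16 were fixed beforehand. No paired analysis was possible because the labels give no replicate numbers and there was 1 library per group. Of 3066 list medians under alternatives 2781 kept their sign, 35 changed it from a called value and 242 moved outside their interval. Of 4418 values of named genes 4210 kept their sign, 44 called values changed it and 796 moved outside their interval. The named genes had by then been limited to fewer contrasts because many more had changed sign. Shares moved outside their interval in 99 of 168 cases and Stra8 levels in 35 of 90.

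The lower glycolysis medians of early meiotic-like over undifferentiated-like cells kept their sign under 19 of 19 alternatives, from -2.63 to -1.42 in the wild-type and from -2.09 to -1.32 in the deficient library. Importer medians did so as well, from -2.34 to -0.40 and from -1.15 to -0.50, and from 0.38 to 1.07 between libraries under 16 of 16 alternatives. In the main setting, however, each of these importer medians lay within the range of matched random lists. The wild-type stage median also had an interval that held 0. Between libraries the matched lists themselves had a median of 0.38, so a positive sign there is not particular to importers. Nuclear oxidative phosphorylation kept its sign under 13 of 19 alternatives in the wild-type (-0.33 to 0.20) and 12 of 19 in the deficient library (-0.18 to 0.11). Meiotic prophase between libraries ran from -0.59 to 0.43, with the same sign under 15 of 16. In the values below, medians and genes are log2 ratios, stage ratios are those over undifferentiated-like cells, Stra8 levels are CPM, and the cause was not tested.

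Under the order of magnitude rule for calling cells, which gave cell numbers alone, 765 cells were kept in the deficient library against 1708, and 2105 in the wild-type library against 2495. Thinned cells gave shares alone. Depth limits differed by class. Sertoli-like cells had a median of 1931 UMIs in the deficient and 13600 in the wild-type library, while early meiotic-like cells had 25709 and 15828. The 62 wild-type cells of the latter class, with 1031282 UMIs in all, limit what can be measured there for genes of low level.

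With a 500 UMI minimum, the named germ share was 17.5% in the deficient library, the early meiotic-like share of named germ cells was 12.8% in the wild-type library and 37.9% in the deficient library and the early meiotic-like Stra8 level was 1063 in the wild-type library. With a 500 UMI minimum, wild-type stage ratios gave nuclear oxidative phosphorylation -0.14, mitosis -0.31, Psma3 -0.18 and Plk1 -0.24 and wild-type cells against the differentiating class gave mitosis -0.49. With a 500 UMI minimum, deficient cells against the differentiating class gave cholesterol synthesis 0.11 and DNA replication 0.089 and differentiating-like cells between the libraries gave mitosis -0.14. With a 500 UMI minimum, early meiotic-like cells between the libraries gave amino acid importers 1.07, proteasome 0.16, meiotic prophase -0.59, Pgam1 0.041, Gapdh 0.30, Psmb1 0.058, Map1lc3a 0.051 and Ube2c 0.67. With a 2000 UMI minimum, the named germ share was 14.8% in the wild-type library and 30.7% in the deficient library and the early meiotic-like share of named germ cells was 17.1% in the wild-type library. With up to 20% mitochondrial UMIs, the named germ share was 13.9% in the wild-type library, the early meiotic-like share of named germ cells was 9.73% in the wild-type library and 29.7% in the deficient library and the early meiotic-like Stra8 level was 1026 in the wild-type library and 51.1 in the deficient library. With up to 20% mitochondrial UMIs, wild-type stage ratios gave mitosis -0.35, retinoid pathway -0.42, Psma3 -0.19, Plk1 -0.35, Ccng1 -0.49 and Crabp1 -0.53 and wild-type cells against the differentiating class gave mitosis -0.96. With up to 20% mitochondrial UMIs, deficient stage ratios gave nuclear oxidative phosphorylation -0.17 and mitochondrial oxidative phosphorylation 0.21. With up to 20% mitochondrial UMIs, early meiotic-like cells between the libraries gave Slc38a2 0.036, Ube2c 0.74 and Btg2 0.13. With doublets kept, the named germ share was 13.9% in the wild-type library and the early meiotic-like share of named germ cells was 16.5% in the wild-type library and 52.99% in the deficient library. With doublets kept, wild-type stage ratios gave Cenpe 0.026.

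At resolution 0.6, the named germ share was 15.8% in the deficient library, the early meiotic-like share of named germ cells was 12.5% in the wild-type library and 34.6% in the deficient library and the early meiotic-like Stra8 level was 1280 in the wild-type library and 51.9 in the deficient library. At resolution 0.6, wild-type stage ratios gave nuclear oxidative phosphorylation -0.28, mitosis -1.15, Psma3 -0.37, Plk1 -2.08 and Ccng1 -1.58 and wild-type cells against the differentiating class gave mitosis -1.21. At resolution 0.6, deficient stage ratios gave nuclear oxidative phosphorylation -0.18, mitochondrial oxidative phosphorylation 0.092, Mki67 -0.062, Plk1 -0.10 and Cdkn1a -0.012. At resolution 1.5, the early meiotic-like share of named germ cells was 8.58% in the wild-type library and 40.1% in the deficient library and the early meiotic-like Stra8 level was 1187 in the wild-type library and 28.3 in the deficient library. At resolution 1.5, wild-type stage ratios gave nuclear oxidative phosphorylation -0.33, mitosis -0.60, Psma3 -0.37 and Plk1 -1.17 and wild-type cells against the differentiating class gave mitosis -0.62. At resolution 1.5, deficient cells against the differentiating class gave cholesterol synthesis 0.0018 and DNA replication 0.049 and differentiating-like cells between the libraries gave mitosis -0.093. With each library clustered alone, the named germ share was 8.42% in the wild-type library and 28.2% in the deficient library, the early meiotic-like share of named germ cells was 10.9% in the wild-type library and 51.6% in the deficient library and the early meiotic-like Stra8 level was 1388 in the wild-type library. With each library clustered alone, wild-type stage ratios gave amino acid importers -2.34, nuclear oxidative phosphorylation -0.25, mitosis -1.04, Psma3 -0.40, Plk1 -2.003, Ccng1 -1.60 and Crabp1 -0.69. With each library clustered alone, wild-type cells against the differentiating class gave mitosis -0.96 and undifferentiated-like cells between the libraries gave mitochondrial oxidative phosphorylation -0.018. With list genes among the variable genes, the named germ share was 11.7% in the wild-type library and 24.7% in the deficient library, the early meiotic-like share of named germ cells was 9.25% in the wild-type library and 32.0% in the deficient library and the early meiotic-like Stra8 level was 1246 in the wild-type library and 46.7 in the deficient library. With list genes among the variable genes, wild-type stage ratios gave nuclear oxidative phosphorylation -0.21, mitosis -0.86, Psma3 -0.41, Plk1 -1.24, Ccng1 -1.86 and Crabp1 -0.43. With list genes among the variable genes, wild-type cells against the differentiating class gave mitosis -1.02 and deficient stage ratios gave mitochondrial oxidative phosphorylation 0.13 and Plk1 -0.30. With list genes among the variable genes, undifferentiated-like cells between the libraries gave mitochondrial oxidative phosphorylation -0.020.

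With cells thinned to 1000 UMIs, the named germ share was 13.4% in the wild-type library and 20.5% in the deficient library and the early meiotic-like share of named germ cells was 75.4% in the deficient library. Under another random seed, the early meiotic-like share of named germ cells was 46.0% in the deficient library and the early meiotic-like Stra8 level was 38.2 in the deficient library. Under another random seed, deficient stage ratios gave mitochondrial oxidative phosphorylation 0.010. Under the first naming version, the named germ share was 20.6% in the deficient library and the early meiotic-like share of named germ cells was 65.8% in the deficient library. Keeping shallow germ clusters under that version, the named germ share was 11.2% in the wild-type library, the early meiotic-like share of named germ cells was 16.5% in the wild-type library and the early meiotic-like Stra8 level was 842 in the wild-type library. Keeping shallow germ clusters under that version, wild-type stage ratios gave Psma3 -0.048 and wild-type cells against the differentiating class gave mitosis -1.06. Keeping shallow germ clusters under that version, differentiating-like cells between the libraries gave mTORC1 components -0.017 and mitosis -0.20. Keeping shallow germ clusters under that version, early meiotic-like cells between the libraries gave amino acid importers 0.90, proteasome 0.020, meiotic prophase -0.41, Gapdh 0.083 and Ube2c 0.15. Under the second naming version, the named germ share was 14.2% in the wild-type library, the early meiotic-like share of named germ cells was 7.08% in the wild-type library and 37.3% in the deficient library and the early meiotic-like Stra8 level was 1282 in the wild-type library and 49.9 in the deficient library. Under the second naming version, wild-type stage ratios gave nuclear oxidative phosphorylation -0.18, mitosis -0.30, Psma3 -0.35, Plk1 -1.56, Ccng1 -0.83 and Crabp1 -0.97. Under the second naming version, wild-type cells against the differentiating class gave mitosis -0.83 and deficient stage ratios gave mitochondrial oxidative phosphorylation 0.040 and Plk1 -0.12.

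Giving unnamed germ clusters their best class, the named germ share was 14.99% in the wild-type library and the early meiotic-like share of named germ cells was 16.6% in the wild-type library. Averaging CPM per cell, the early meiotic-like Stra8 level was 639 in the wild-type library and 37.7 in the deficient library. Averaging CPM per cell, early meiotic-like cells between the libraries gave meiotic prophase -0.30. After subtraction of free RNA, Sertoli-like cells between the libraries gave meiotic prophase -0.59. After subtraction with the 200 to 500 UMI profile, Sertoli-like cells between the libraries gave meiotic prophase -0.35. With a pseudocount of 10, deficient stage ratios gave glycolysis -1.32. In the shared cluster alone, early meiotic-like cells between the libraries gave meiotic prophase 0.43, mitosis 1.01 against 0.0060, Slc16a1 0.049, Ung -0.13, Bub1 0.49 and Ube2c 0.41.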

Other observations

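Of the tests in this part, the Sertoli-like comparisons of Stra8 and of stress genes were chosen after the values had been seen, while the count of Stra8 UMIs per cell and the peritubular myoid-like stress median were chosen before. Stra8 had 213 UMIs in 231 early meiotic-like cells of the deficient library, with at least 1 UMI in 115 of them (49.8%), against 587 UMIs in 49 of 62 wild-type cells (79.0%). Free RNA as the whole source is argued against by Sertoli-like cells of the deficient library, whose upper limit of 2.743 CPM lay below the lower limit of 28.5 CPM in early meiotic-like cells. Admixed wild-type cells are argued against as well, since 0% of the UMIs lay in cells at or above the wild-type level, where 27 of 62 wild-type cells held 87.2% of theirs. Transcription of an altered gene could leave such reads and stays a hypothesis, as the labels do not say which part of Stra8 is altered, and age was not tested.

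Dissociation stress genes, the immediate early and heat shock genes that respond to handling of tissue, had lower medians in the deficient library in 7 classes, with intervals that held 0 in the undifferentiated-like (-0.32, -1.31 to 0.032) and Leydig-like cells (-0.73, -2.70 to 0.24). The other medians included -1.53 in early meiotic-like, -2.0 in differentiating-like, -1.25 in Sertoli-like and -2.58 in interstitial stromal-like cells. A difference shared by the cell types of a library was met in peritubular myoid-like cells, at -1.274, below the bound of -0.5 set before. A difference of germ cells alone is argued against by Sertoli-like cells, whose upper limit was -0.8904. Handling, age and genotype could each give a shared difference and stay open, since all 3 go with the library.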
